A study of Rattus norvegicus with 42 samples.

How the data were processed

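Gene expression was measured in whole lung of 22 male Sprague-Dawley rats on 42 one-colour oligonucleotide arrays with 9911 gene probes. Per the labels' protocols, total RNA was amplified to cRNA together with spiked-in bacterial RNA, labelled with Cy5 and hybridised to a CodeLink rat array. The labels number the rats and give 1 to 5 arrays per rat, so the rat was taken as the replicate and its arrays were averaged. The sample descriptions also hold a number for the animal, and there rat 20 (sustained day 14) and rat 22 (sustained day 30) share the number 18; the labels' rats and days were followed. The array code in the labels ends in I, IV or V, and each of these 3 array series carried a project name of its own in the file headers. The series were therefore treated as batches of 9, 17 and 16 arrays.

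The deposited scanner files hold 1 background-subtracted linear intensity per spot. Per the file headers they were made with CodeLink Expression Analysis 4.1.0.4163, and in the deposited values this intensity equalled the spot mean minus the median local background. No normalization between arrays had been applied to it. The authors' processed log2 values, deposited as a series table, were used only as an alternative. In that table every array of the room-air and intermittent groups had a median of 7.95 and a minimum of 4.36, and every sustained-hypoxia array a median of 7.88 and a minimum of 4.06. The sustained-hypoxia arrays thus have another scale in this table, with a median difference from room air over all probes of -0.08. How these values were scaled is not given in the sources used here.

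Spots flagged as contaminated, irregular or masked were left out (median 1.98% of gene probes per array, range 1.19% to 3.75%), and spots flagged near background or saturated were kept. Intensities were scaled to the array median, given a floor of 10 on the scaled intensity, log2-transformed and quantile-normalized. A probe was kept if it was above the scanner's detection limit in more than 50% of the arrays of at least 3 rats, which left 9287 probes, and 6135 were detected in all 22 rats. Array series was removed with limma's removeBatchEffect with rat as the design, so that it was estimated only within rats, and the arrays of each rat were then averaged. Fold changes are differences of these log2 values, and those of dim probes are compressed by the floor. The offset of series I came from rats 1, 3 and 14, the only rats with arrays of series I and of another series. It was also applied to intermittent rats 4, 5, 7, 9, 10 and 13, which were on series I only. Its error is shared by these rats and is not part of the SE or p-values.

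Genes were named from the platform table, which gave 1 symbol to 7095 gene probes and several to 82, and did not list 2734. Symbols were updated through Entrez identifiers with the RefSeq gene table of assembly GRCr8, used for names only. The gene identifier in the scanner files equalled that of the platform table for 2759 of the 2835 probes that had both (97.3%). Probes without 1 symbol are given by their number, and no coordinates were used. Epas1, Nos3 and the alpha and beta globin genes, fixed in advance for description, had no named probe.

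Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). The model had 11 groups (room air and 5 days of each exposure), 22 rats and 11 residual degrees of freedom, with eBayes using a mean-variance trend and robust variances. The contrasts over all days weighted the 5 days equally. Single days were tested where they had at least 2 rats, and the 1-rat groups were assumed to vary like the others. Time trends were slopes on log2 of the day within each exposure. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all probes of a comparison, with a threshold of 0.05, and SE is limma's moderated standard error. There was 1 room-air group and no room-air group matched to each day.

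All 32 gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe per gene (the one with the highest mean) and only probes measured in all rats. They cover oxygen response, metabolism, matrix, stress, immune cells, lung cell types, and tissues that a lung sample could carry along. Each list was tested again with an estimated correlation. It was also tested with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. List medians are over all measured members.

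The named genes followed a rule set before the data were examined. For the 3 comparisons over all days it took up to 10 passing genes per direction, those with the largest fold change, and required the same sign in every rat of an exposure compared with room air. It took up to 3 per direction for single days and for sustained days 1 to 7, up to 5 per direction for trends, and the 3 named genes with the smallest p where none passed. From each list described it took up to 4 members with the smallest p, and 11 genes were fixed by name. Members named for a slope, and the other single genes named in the closing part, were chosen after their values were seen. Unnamed probes are given where few probes passed.

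The test was tried on simulated values for 8059 probes with known changes. For intermittent hypoxia against room air it recovered 26% of 50 genes changed by 1 log2 unit and 78% of 50 changed by 2. For sustained hypoxia it recovered 22% and 62%, with 0 false calls in either. A simulated list of 20 genes shifted by 0.5 log2 units was found, and 0 of 30 unshifted lists were called. The simulated genes varied independently of each other, while the estimated correlation within the skeletal muscle list was 0.56. The simulation therefore does not tell how often correlated genes are called falsely.

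Alternatives fixed before the data were examined covered the array series, array-level fits with rat as a random block, normalization, background, the authors' processed values, filters, flags, weights, the grouping of days, the variance model and each rat left out in turn. Some alternatives were chosen after the data were seen. These were leaving out 9 dim arrays (median gene-probe intensity under 150), also with array series IV and V only, splitting room-air arrays by their code, and naming further list members through the gene identifier in the scanner files. List tests of the slopes were also added then. The number of arrays, and above all of rats, limits the precision.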

Results

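The study asked how intermittent and sustained hypoxia change gene expression in the rat lung over time. Rats in intermittent hypoxia breathed 10% and 21% oxygen in alternating phases of 90 s for 12 h of each day, and rats in sustained hypoxia breathed 10% oxygen throughout. Lungs were taken after 1, 3, 7, 14 or 30 days. Intermittent hypoxia had 12 rats (3, 2, 3, 3 and 1 at these days; 16 arrays), sustained hypoxia had 7 (1, 1, 1, 2 and 2; 12 arrays), and room air had 3 (14 arrays).

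The arrays differed in brightness. The median gene-probe intensity was between 65.0 and 499 (42 arrays), and the share of spots flagged near background was between 5.59% and 26.0%. The median intensity was under 150 on 9 arrays: 1 of 14 in room air, 5 of 16 in intermittent and 3 of 12 in sustained hypoxia. Among the 3 rats of intermittent day 7, 3 of the 4 arrays were dim, and rats 10 and 11 had only dim ones. No array of sustained hypoxia belonged to series I, which held 2 room-air and 7 intermittent arrays.

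**Figure D1:**
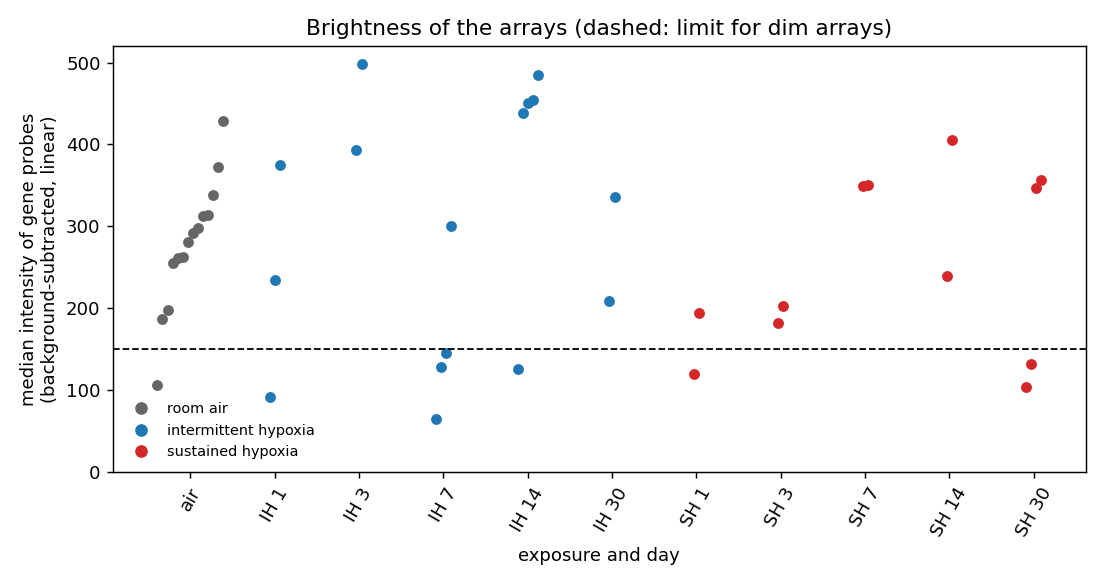
Median background-subtracted intensity of the gene probes (y axis, linear scanner units) of each of the 42 arrays, by exposure and day (x axis; IH intermittent, SH sustained); points within a group are spread sideways for visibility. The dashed line marks 150, and 9 arrays lie below it, 3 of them at intermittent day 7.

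Sustained hypoxia raised 4 named genes over all days against room air. Ntrk2, the receptor for brain-derived neurotrophic factor, was 10.1-fold higher (log2 3.33, SE 0.38, adjusted p = 0.0050), at a mean log2 intensity of 8.19 ± 0.72 (SD, n = 7) against 5.05 ± 0.31 (SD, n = 3). Glp1r, the receptor for glucagon-like peptide 1, was 2.97-fold higher (log2 1.57, SE 0.21, adjusted p = 0.014). Heyl, a transcriptional repressor downstream of Notch, was 2.68-fold higher (log2 1.42, SE 0.22, adjusted p = 0.029), as was Adamts1, a secreted protease of the matrix (log2 1.42, SE 0.22, adjusted p = 0.025). Probe 2334, which had no gene symbol here, was 2.45-fold higher (adjusted p = 0.025). All 5 were higher in 7 of 7 rats, and they were the only calls among 9287 probes (355 at unadjusted p under 0.05).

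Within array series IV these 5 were higher by log2 3.59 (Ntrk2), 1.67 (Glp1r), 1.53 (Heyl), 1.38 (Adamts1) and 1.28 (probe 2334), and within series V by 3.09, 1.52, 1.32, 1.44 and 1.31; all but Heyl (adjusted p = 0.079 and 0.16) passed in both. Both series held the same room-air and sustained rats, save rat 19 (series IV) and rat 20 (series V). Their agreement is thus mostly one of repeat arrays and not of separate animals. With normexp background correction Ntrk2 was higher by log2 2.06. The Heyl call passed in 11 of 18 other settings and ended, among others, with the authors' processed values (adjusted p = 0.085), with median centring (0.086), with series IV and V only (0.057) and without rat 13, 18 or 19 (0.063, 0.13 and 0.080). The count of 5 rested on 3 control rats: it was 0 without room-air rat 1, 0 without rat 2 and 1 without rat 3, it was 2 without intermittent rat 7, 8 or 14, and it was 9 without rat 9 and 8 without rat 11. It was 0 when all rats of an exposure were pooled over days, 2 with median centring in place of quantile normalization (Ntrk2 and Glp1r), 15 and 10 within series IV and V, and 196 in an array-level fit with rat as a random block.

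**Figure D2:**
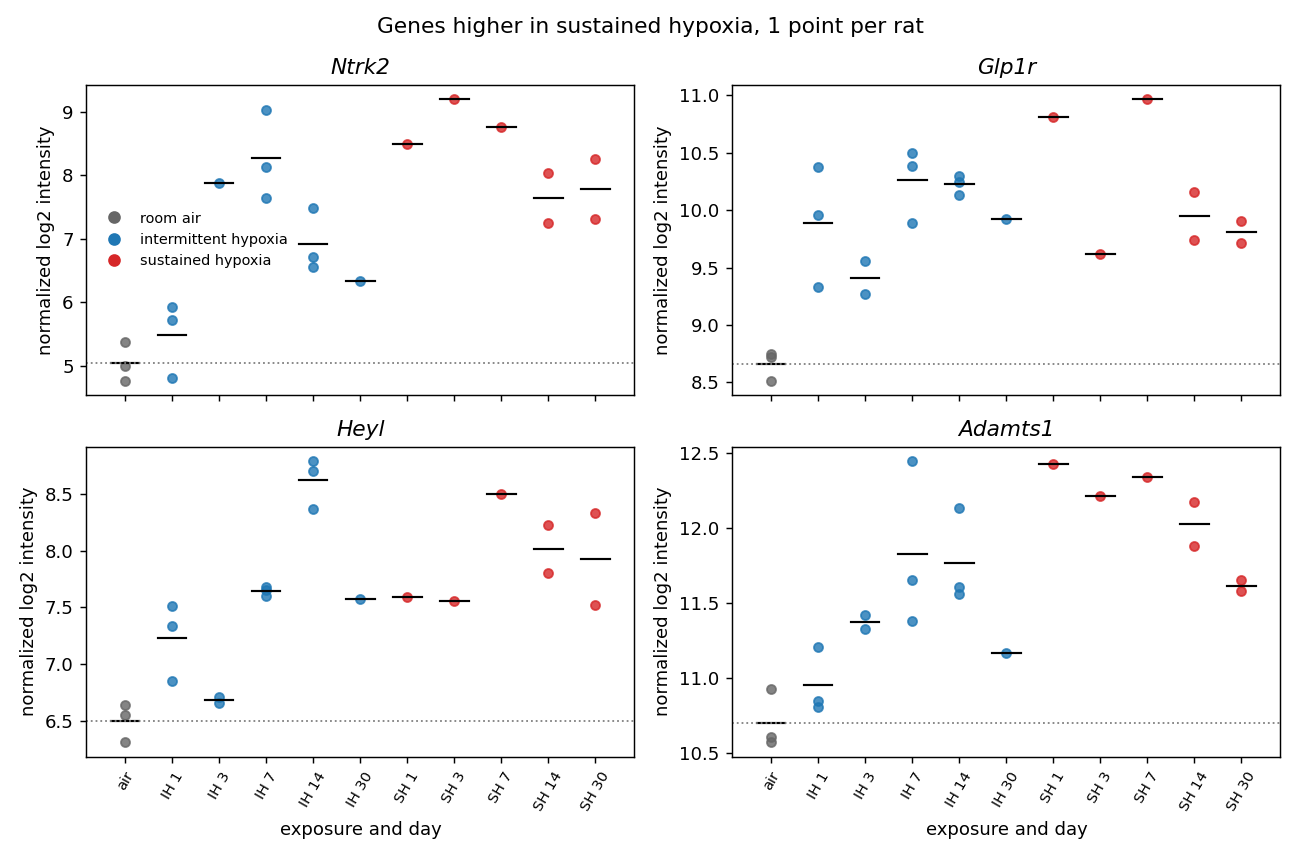
Normalized log2 intensity (y axis) of Ntrk2, Glp1r, Heyl and Adamts1 by exposure and day (x axis; IH intermittent, SH sustained), with 1 point per rat, bars at group means and a dotted line at the room-air mean. All 7 sustained-hypoxia rats lie above the room-air mean for each gene.

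Among the gene lists, 6 rose and 2 fell in sustained hypoxia at the preset correlation, and 0 of 32 were called with an estimated correlation (lowest adjusted p = 0.58 with an estimated correlation) or with fry (lowest 0.60). No member of these 8 lists passed over all genes, and adjusted over the list alone 1 neutrophil and 1 glycolysis gene passed. The glycolysis list rose (14 members, median log2 0.20, adjusted p = 0.037), with Pfkl, a phosphofructokinase, at log2 1.48 (SE 0.33), Slc16a3, a lactate exporter, at 0.79 (SE 0.27), Hk1 at 0.59 (SE 0.22) and Ldha at 0.36 (SE 0.16), each higher in 7 of 7 rats. The cell cycle list rose (24 members, median log2 0.42, adjusted p = 0.0022), with Cks2 at log2 1.19 (SE 0.48), Mki67 at 1.15 (SE 0.55), Prc1 at 1.00 (SE 0.39) and Cenpf at 0.69 (SE 0.27). The erythroid list rose (13 members, median log2 0.38, adjusted p = 0.0022), with 13 of 13 members higher, among them Alas2, which starts haem synthesis in red-cell precursors, at log2 1.18 (SE 0.65).

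The matrix list rose in sustained hypoxia (40 members, median log2 0.20, adjusted p = 0.015; adjusted p = 0.82 with an estimated correlation), with osteopontin, Spp1, at log2 1.99 (SE 0.98) and versican, Vcan, at 0.79 (SE 0.37). The neutrophil list rose (12 members, median log2 0.39, adjusted p = 0.018; adjusted p = 0.58 with an estimated correlation), led by Defa5 at log2 1.73 (SE 0.44; higher in 4 of 7 rats) and S100a9 at 0.73 (SE 0.33). The platform table names this probe Defa5 and the scanner files describe it as defensin RatNP-1, and since defensin copies are nearly alike, which of them it measures is not settled. The monocyte and macrophage list rose (21 members, median log2 0.12, adjusted p = 0.034; adjusted p = 0.58 with an estimated correlation), with the complement genes C1qb at log2 0.72 (SE 0.21), C1qc at 0.60 (SE 0.25) and C1qa at 0.52 (SE 0.22). The interferon list fell (21 members, median log2 -0.38, adjusted p = 0.0022; adjusted p = 0.64 with an estimated correlation), with Irf7 at log2 -0.96 (SE 0.29), Oasl at -0.96 (SE 0.42) and Eif2ak2 at -0.91 (SE 0.38), while Rsad2 stood at 0.79 (SE 0.31). The alveolar type II list fell (12 members, median log2 -0.32, adjusted p = 0.0080; adjusted p = 0.58 with an estimated correlation), with 11 of 12 members lower, among them Etv5 at log2 -1.04 (SE 0.64) and Il33 at -0.87 (SE 0.32).

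The interferon call passed with any 1 rat left out (highest adjusted p = 0.023), and the other 7 list calls depended on single rats. Pooling the days ended the neutrophil (adjusted p = 0.45), glycolysis (0.16), cell cycle (0.12), macrophage (0.075) and matrix (0.060) calls, and keeping only probes detected in all rats ended the neutrophil (0.62), matrix (0.051) and macrophage (0.051) calls. Without rat 16 (day 1) the neutrophil median was 0.09 (adjusted p = 0.84) and the glycolysis median 0.10 (adjusted p = 0.27). The neutrophil call also ended without rat 2, 6 or 18, the glycolysis call without rat 1, 2, 4, 9, 10, 12, 17 or 18, and the macrophage call without rat 1, 2, 9, 12, 18 or 21. Without rat 17 (day 3) the calls of the erythroid (adjusted p = 0.069), cell cycle (0.18), matrix (0.15) and alveolar type II (0.071) lists ended, and the matrix call ended without rat 1, 18 or 21 as well. The number of lists called was 5 without rat 1 and 4 without rat 17 or 18. Within array series IV and within series V, which held mostly the same rats, the interferon, cell cycle, erythroid and alveolar type II lists passed in both. The neutrophil (adjusted p = 0.16 and 0.31), glycolysis (0.11 and 0.39) and matrix (0.083 and 0.053) lists passed in neither, and the macrophage list passed only in series IV (0.028 and 0.68). The glycolysis and the macrophage list each passed in 7 of 21 other settings, and the glycolysis list did not pass, among others, with rat as a random block (adjusted p = 0.063), with median centring (0.075), with the authors' processed values (0.054) or without the dim arrays (0.090).

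**Figure D3:**
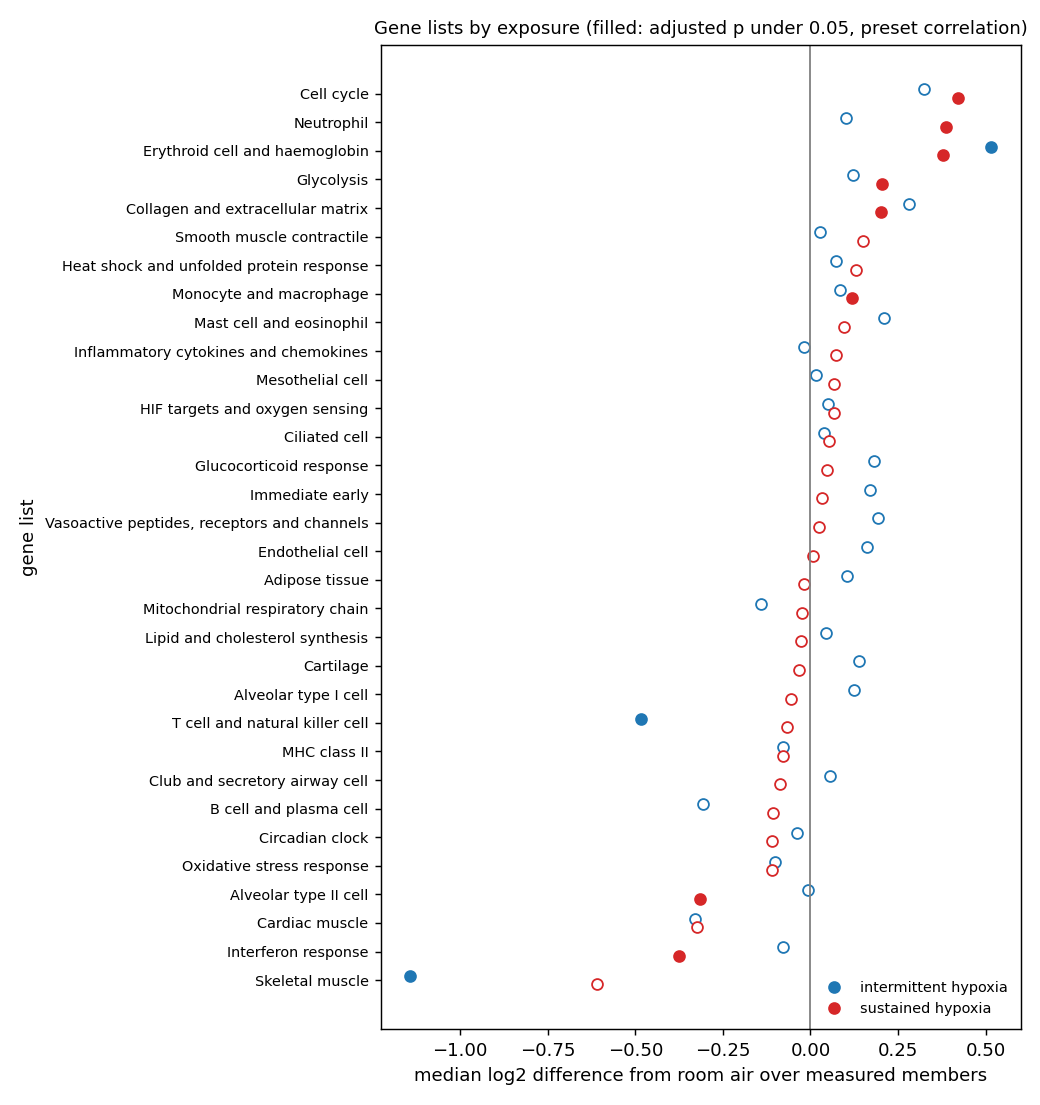
Median log2 difference from room air (x axis) over the measured members of each of 32 gene lists (y axis), for intermittent (blue) and sustained hypoxia (red); filled points have an adjusted p under 0.05 at the preset correlation. The skeletal muscle list has the lowest median in intermittent hypoxia, at -1.14.

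Intermittent hypoxia gave Glp1r, Ntrk2 and Heyl the smallest p-values over all days, and none of them passed. Glp1r stood at log2 1.28 (SE 0.20, adjusted p = 0.13) and was higher in 12 of 12 rats. Ntrk2 stood at log2 1.93 (SE 0.36, adjusted p = 0.53; higher in 10 of 11 rats) and Heyl at 1.05 (SE 0.21, adjusted p = 0.53; 12 of 12 rats). By limma on rat means 0 of 9287 probes passed, with 509 at unadjusted p under 0.05. The array-level fit with rat as a random block called 206, and weighting rats by their arrays gave 37. The count was 1 without rat 6 and 2 without rat 11. Within series I, IV and V the counts were 1, 15 and 1. Without the 9 dim arrays, an alternative chosen after the data were seen, the count was 105.

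The erythroid list rose in intermittent hypoxia (13 members, median log2 0.52, adjusted p = 7.4e-04; adjusted p = 0.75 with an estimated correlation). Kel, a red-cell surface protein, stood at log2 1.32 (SE 0.55) and Fech, which inserts iron into haem, at 0.63 (SE 0.22; higher in 12 of 12 rats). The T and natural killer cell list fell (23 members, median log2 -0.48, adjusted p = 0.0010; adjusted p = 0.75 with an estimated correlation), with 21 of 23 members lower. The granzymes Gzmb and Gzma stood at log2 -1.04 (SE 0.39) and -0.66 (SE 0.21), each lower in 12 of 12 rats, and the killer-cell receptor gene Klrd1 at -0.62 (SE 0.22). The skeletal muscle list fell (15 members, median log2 -1.14, adjusted p = 0.0012; adjusted p = 0.75 with an estimated correlation), with Tnni2, a troponin, at log2 -3.27 (SE 1.63). In room air the median of this list stood at 0.99 and 0.92 above the group mean in rats 1 and 3 and at -1.66 in rat 2, so that the controls themselves differed. No member of the 3 lists passed over all genes or adjusted over the list alone.

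The skeletal muscle call ended without room-air rat 1 (median log2 -0.70, adjusted p = 0.071) or rat 3 (-0.50, adjusted p = 0.12) and without the dim arrays (-0.92, adjusted p = 0.13), and the T and natural killer cell call ended without room-air rat 3 (-0.24, adjusted p = 0.054). Within series I, IV and V the erythroid medians were 0.28, 0.46 and 0.74, the T and natural killer cell medians -0.58, -0.45 and -0.47, and the skeletal muscle medians -1.90, -1.42 and -1.54. The erythroid list passed only in series V, and the T and natural killer cell list did not pass there (adjusted p = 0.18). The number of lists called was 5 without rat 1 or rat 4.

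The difference between the exposures was tested directly. Probe 14006, which had no gene symbol here, was lower in intermittent than in sustained hypoxia (log2 -1.60, SE 0.21, adjusted p = 0.014), at 3.91 ± 0.62 (SD, n = 12) against 5.16 ± 1.80 (SD, n = 7). It was the only call, with 1045 probes at unadjusted p under 0.05. Cth, an enzyme of cysteine synthesis, stood 2.33-fold higher in intermittent hypoxia (log2 1.22, SE 0.19, adjusted p = 0.082), Schip1 at log2 0.70 (SE 0.12, adjusted p = 0.11) and C11h21orf91 at -1.09 (SE 0.18, adjusted p = 0.089), and none of the 3 passed. Ntrk2 stood at log2 -1.40 (SE 0.28, adjusted p = 0.23).

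Probe 14006 was flagged near background on 6 of 14 room-air, 12 of 16 intermittent and 5 of 12 sustained arrays. Its call ended without rat 16 (log2 -0.87, adjusted p = 0.26), 17 (-1.26, 0.17), 19, 20 or 22. It also ended with series IV and V only (adjusted p = 0.075) and with the days pooled (0.22), and with normexp background correction the difference was -0.76. It stood at -1.65 within series IV and -1.59 within series V (adjusted p = 0.028 and 0.095). The count of calls was 398 without intermittent rat 6 (1 dim array, labelled day 1 with a file header that reads 6 HR), 6 without rat 15, 3 without rat 10 and 2 without rat 11. It was 341 within series IV and 0 within series V, 121 with rat as a random block and 1895 without the dim arrays. Of the 32 lists, 0 were called by camera. The glucocorticoid response list had the lowest adjusted p (0.060; median log2 0.23, 15 of 19 members higher in intermittent hypoxia), followed by alveolar type II (0.095; median 0.27), and fry called 0 (lowest 0.24). The count of lists was 3 without rat 18, 2 without rat 10, and 1 without rat 3, 11, 12, 14, 16, 17 or 20.

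Genes fixed by name did not pass over all days in either exposure on all arrays. Dbp, an output gene of the circadian clock, stood at log2 -2.08 (SE 0.54; lower in 10 of 11 rats) in intermittent and -2.00 (SE 0.57; 7 of 7 rats) in sustained hypoxia. Bmal1, a core clock gene, stood at 0.64 (SE 0.27) and 0.73 (SE 0.28), and Per2 at -0.07 (SE 0.39) and -0.16 (SE 0.42). Dbp was the 1 clock gene lower in intermittent hypoxia adjusted over the list alone, and 2 were lower in sustained hypoxia. The hours at which lungs were taken are not given in the sources used here. Vegfa, the main growth factor of blood vessels, stood at -0.37 (SE 0.34) and -0.39 (SE 0.36), Edn1, which encodes the vasoconstrictor endothelin, at 0.60 (SE 0.38) and 0.37 (SE 0.42), and Hif1a at -0.20 (SE 0.53) and 0.06 (SE 0.57). The list of HIF targets and oxygen sensing had medians of 0.05 and 0.07 over 25 members (adjusted p = 0.53 and 0.52).

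Early sustained hypoxia raised Ntrk2, Glp1r and Adamts1. Over days 1, 3 and 7 (3 rats, 1 per day), Ntrk2 was 13.7-fold higher than in room air (log2 3.77, SE 0.44, adjusted p = 0.0068), Glp1r 3.49-fold (log2 1.80, SE 0.25, adjusted p = 0.016) and Adamts1 3.08-fold (log2 1.62, SE 0.25, adjusted p = 0.039), each in 3 of 3 rats. Within series IV and V, on repeat arrays of the same 3 rats, Ntrk2 stood at 3.89 and 3.67, Glp1r at 1.82 and 1.84, and Adamts1 at 1.61 and 1.62. These were the only 3 calls (361 at unadjusted p under 0.05), and the count was 0 without room-air rat 1 or 2, 1 without rat 3 or 16, 5 without rat 9, and 6 without rat 10 or 11. The Adamts1 call ended with 15 of the 22 rats left out in turn (all but rats 5, 6, 9, 10, 11, 12 and 15), with median centring (adjusted p = 0.17) and without trend and robust variances (0.063), and the Glp1r call also without rat 18 (0.091). With normexp background correction Ntrk2 was higher by log2 2.42. The count was 221 with rat as a random block.

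The days with 1 rat were not tested on their own. Above the room-air mean, Ntrk2 stood at log2 3.44, 4.16 and 3.72 in the rats of sustained days 1, 3 and 7 and Glp1r at 2.15, 0.96 and 2.31. In the rat of intermittent day 30 Ntrk2 stood at 1.29 and Heyl at 1.08.

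Later sustained hypoxia gave no call. At day 14 (2 rats) the lowest adjusted p was that of probe 2334 (0.056). Among named genes Ntrk2 stood at log2 2.60 (SE 0.49, adjusted p = 0.38), Heyl at 1.52 (SE 0.29, adjusted p = 0.38) and Adamts1 at 1.32 (SE 0.28, adjusted p = 0.59). At day 30 (2 rats) Ntrk2 stood at log2 2.74 (SE 0.49), Heyl at 1.43 (SE 0.29) and Pgm2l1 at -1.07 (SE 0.22), each with an adjusted p of 0.45. Limma called 0 probes at either day, with 265 and 296 at unadjusted p under 0.05, and the array-level fit called 16 and 56 with rat as a random block. Without the dim arrays 166 and 5 were called. At day 14 the count was 2 without intermittent rat 6 and 1 without rat 5, 10 or 11.

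Day 7 of intermittent hypoxia had the most calls of the single days tested on all arrays, with 174 probes higher and 29 lower than in room air (3 rats; adjusted p between 0.032 and 0.049; 2482 at unadjusted p under 0.05). The days were not tested against each other, and without the dim arrays 217 probes passed at day 3. Ntrk2 was 9.34-fold higher (log2 3.22, SE 0.44), Prom1, a membrane protein of progenitor and epithelial cells, 3.97-fold (log2 1.99, SE 0.45) and Tcam1 3.14-fold (log2 1.65, SE 0.33). Mob4 was lower by log2 -3.51 (SE 0.51), Dbp by -3.01 (SE 0.67) and Eomes, a transcription factor of killer lymphocytes, by -2.38 (SE 0.47). All 6 went the same way in 3 of 3 rats. Of its 4 arrays, 3 were dim.

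The day-7 count was 1024 without rat 9, 1 without rat 10 and 367 without rat 11. It was 0 without any 1 of room-air rats 1 to 3, rat 14, 21 or 22, and 1, 1, 2, 5 and 5 without rats 7, 8, 13, 19 and 20. It was 464, 726 and 407 without rats 5, 6 and 12. Within series I, IV and V it was 1, 446 and 1, where series IV and V each held 1 day-7 array, both dim and both of rat 11. With the authors' processed values it was 2, and Tcam1, Dbp, Prom1 (adjusted p = 0.059 each) and Eomes (log2 -1.48, adjusted p = 0.097) did not pass. Eomes did not pass with normexp background correction either (log2 -0.81, adjusted p = 0.071), where Mob4 was lower by log2 -2.35 and Ntrk2 higher by 2.02. Dbp and Prom1 did not pass with median centring (adjusted p = 0.070 and 0.051). Prom1 stood at log2 2.09, 2.34 and 0.38 within the 3 series, and Mob4 at -3.19, -4.91 and -3.24. Without the dim arrays 241 probes passed on rat 9 alone, 61 of which were among the 203.

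Heyl rose at day 14 of intermittent hypoxia. It was 4.36-fold higher (log2 2.13, SE 0.26, adjusted p = 0.0082; 3 of 3 rats), at log2 2.06, 2.19 and 1.73 within series I, IV and V (adjusted p = 0.55, 0.070 and 0.34), and it was the only call (438 at unadjusted p under 0.05). The call ended without room-air rat 1, 2 or 3 or without rat 12 or 13, and the count was 2, 3 and 4 without rats 4, 6 and 11. At day 3 (2 rats) Alox15, a lipoxygenase, stood at log2 4.14 (SE 0.81), Car2, a carbonic anhydrase, at 2.11 (SE 0.42), and Tk1, measured in 1 of the rats, at 2.95 (SE 0.51), each with an adjusted p of 0.39. At day 1 (3 rats, of which rat 6 has a file header that reads 6 HR where its label gives 1 day) Tpp1, a lysosomal peptidase measured in 2 of them, stood at log2 -2.26 (SE 0.42), Glp1r at 1.23 (SE 0.25), and Pias1, measured in 1, at -1.32 (SE 0.25), each with an adjusted p of 0.36. Limma called 0 probes at days 1 and 3 (563 and 468 at unadjusted p under 0.05), and the array-level fit called 86 and 116 with rat as a random block. At day 1 the count was 54 without rat 5, 7 without rat 6 and 2 without rat 4, and 1 without rat 10 or 11; at day 3 it was 2 without rat 5 and 1 without rat 8.

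Time courses were tested as slopes on log2 of the day. In sustained hypoxia Defa5 fell by 1.09 per doubling of the day (SE 0.16, adjusted p = 0.011) and probe 14006 fell by 0.90 (SE 0.15, adjusted p = 0.024). Defa5 was highest in rat 16 (day 1), and its probe was near background on 8 of 14 room-air, 8 of 16 intermittent and 5 of 12 sustained arrays. Without rat 16 neither passed (slopes -0.77 and -0.69, adjusted p = 1.00), and without rat 17 or 21 probe 14006 did not (adjusted p = 0.100 and 0.12). Within series IV and V Defa5 had slopes of -1.08 and -1.08 (adjusted p = 0.17 and 0.078) and probe 14006 of -0.92 and -0.89 (0.17 and 0.12). With normexp background correction the slopes were -0.67 and -0.47. These were the only 2 calls (392 at unadjusted p under 0.05); the count was 4 without rat 10, 1 without rat 21, and 0 with the day taken without a logarithm. In intermittent hypoxia Tpp1 had a slope of 0.62 (SE 0.12, adjusted p = 0.46), Ppp1r13b 0.26 (SE 0.06, adjusted p = 0.46) and Idi1, of cholesterol synthesis, -0.36 (SE 0.08, adjusted p = 0.47). None passed (663 at unadjusted p under 0.05; 4 with rat as a random block, and 3 without rat 5). No slope differed between the exposures by limma (331 at unadjusted p under 0.05; 3 with rat as a random block). The smallest p-values of named genes there were those of Itga6 (0.36, SE 0.08), Defa5 (0.88, SE 0.21) and Rpl6 (-1.11, SE 0.28), with adjusted p between 0.990 and 0.996.

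**Figure D4:**
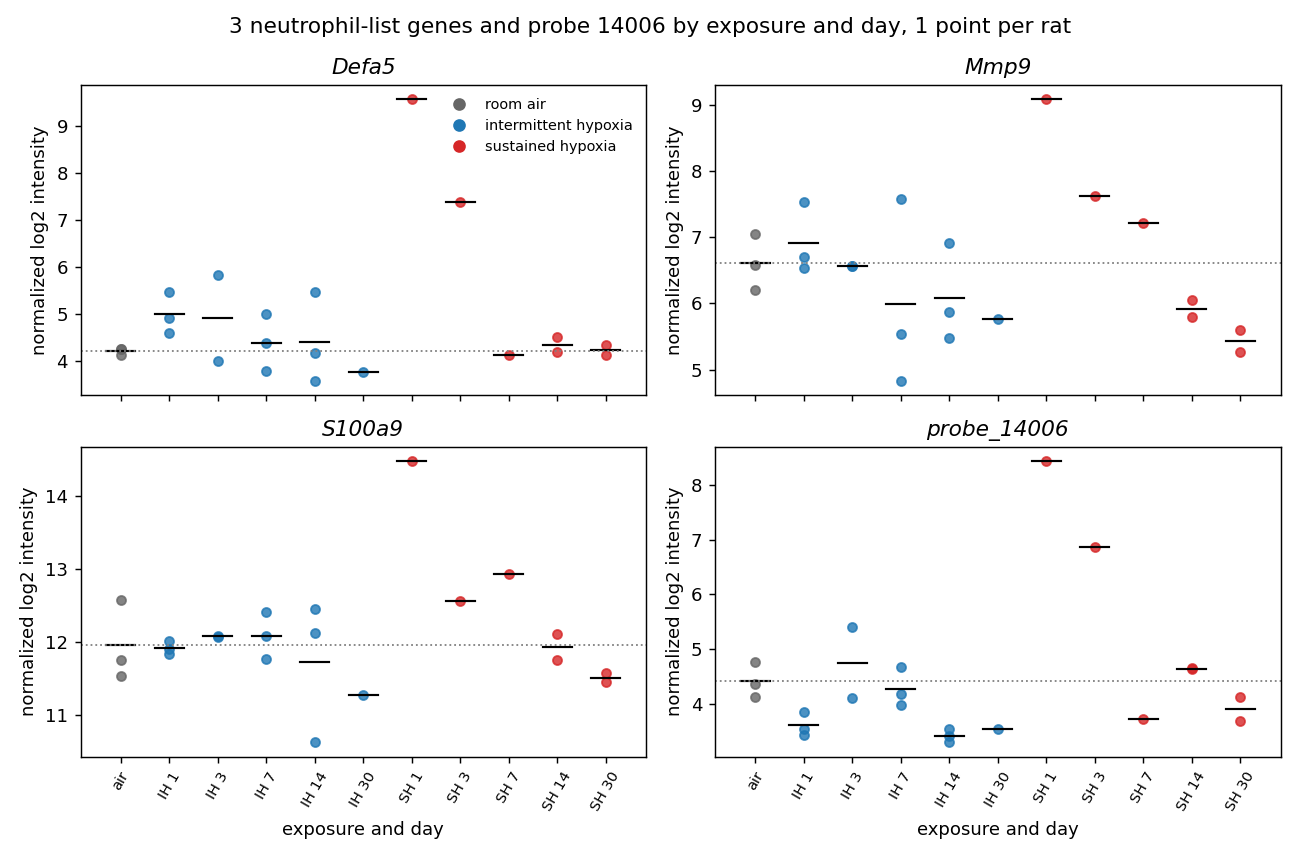
Normalized log2 intensity (y axis) of Defa5, Mmp9, S100a9 and probe 14006 by exposure and day (x axis; IH intermittent, SH sustained), with 1 point per rat, bars at group means and a dotted line at the room-air mean. In each panel the 1 rat of sustained day 1 has the highest value.

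Without the 9 dim arrays (3 room-air, 8 intermittent and 7 sustained rats; chosen after the data were seen), more genes passed. In intermittent hypoxia 62 rose and 43 fell. Ccn2, a matrix-associated growth regulator, stood at log2 1.64 (SE 0.20, adjusted p = 0.0049) and the matrix proteoglycan Bgn at 1.26 (SE 0.25, adjusted p = 0.036), each in 8 of 8 rats; on all arrays both stood at 1.14 and did not pass (adjusted p = 0.98 and 0.93). Cyp26b1, which degrades retinoic acid, stood at log2 1.58 in intermittent and 1.53 in sustained hypoxia (adjusted p = 0.022 and 0.020). Oasl, an interferon-induced gene, stood at log2 -1.18, Nkg7, of killer-cell granules, at -1.06 and Blk, a kinase of B cells, at -1.02, against -0.87, -0.75 and -0.99 on all arrays, where none of the 3 passed. The T and natural killer cell list was lower (median log2 -0.55, adjusted p = 0.0022; adjusted p = 0.82 with an estimated correlation), and the interferon (adjusted p = 0.14) and B cell (0.47) lists did not pass. The glucocorticoid response (median log2 0.29, adjusted p = 0.0022), matrix (0.26, 0.026) and erythroid (0.40, 0.036) lists were higher. With an estimated correlation their adjusted p was 0.54, 0.82 and 0.82. Dbp was lower at log2 -2.30 (SE 0.39, adjusted p = 0.037).

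In sustained hypoxia without those arrays 40 rose and 51 fell, and the 5 probes called on all arrays were among them. Depp1 and Nrn1 stood at log2 1.92 and 1.79 (adjusted p = 0.010 and 0.0082), and the activin-binding Fst at 1.75 and 1.56 by its 2 probes (adjusted p = 0.0022 and 0.0059). In intermittent hypoxia these 2 Fst probes stood at 0.72 and 1.31, and the first did not pass (adjusted p = 0.084 and 0.021). Lyve1, a hyaluronan receptor of lymphatic vessels, was lower in both exposures, at log2 -1.69 in sustained (adjusted p = 0.0019) and -1.03 in intermittent hypoxia (adjusted p = 0.032). Between the exposures 1037 probes were higher and 858 lower in intermittent hypoxia. The fatty-acid transporter Cd36 stood at log2 2.43 (SE 0.18) and the glycolytic enzymes Pkm and Eno1 at 2.02 (SE 0.24) and 1.99 (SE 0.36), each in 8 of 8 rats. The glycolysis list did not pass there (median log2 -0.37, adjusted p = 0.73), with 2 members passing higher and 5 passing lower. The proliferation gene Mki67 stood at -1.42 (SE 0.15; lower in 6 of 8 rats) and Prf1, the pore-forming protein of killer cells, at -1.32 (SE 0.16; 7 of 8 rats). On all arrays Cd36 and Pkm stood at log2 1.96 and 1.62, and Mki67 and Prf1 at -0.85 and -0.85, and these 4 (adjusted p between 0.29 and 0.44) and Eno1 (0.39) did not pass. With array series IV and V only Mki67 stood at -0.23.

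The fold changes of the 2 exposures against the shared room-air rats had a correlation across 8059 probes of 0.475, against 0.720 for simulated unchanged groups that share these controls. Their covariance was 0.058 against 0.115 in the simulation, and 63.6% of probes had the same sign against 75.7%. Probes are not independent replicates, and 3 control rats cannot be split into parts of 2. The simulation gave every rat the same spread, although room-air rats were means of 4 or 5 arrays and exposed rats of 1 to 3. It may thus overstate what shared controls give. The lower observed values therefore do not show that the exposures agree less than by chance. Without the dim arrays the correlation was 0.345 against 0.693 in the simulation, and 59.1% of probes had the same sign against 74.2%. There 15 probes passed as higher and 9 as lower in both exposures, and how many the shared controls alone would give was not tested.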

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

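The tests of dim arrays, single rats, array series and labelling strength below, and all counts of other splits of the rats, were chosen after the results were seen in part.

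At day 7 of intermittent hypoxia 203 probes passed, among them Ntrk2, Mob4 and Dbp, while 3 of the 4 arrays were dim. A candidate explanation is the dimness itself: within 4 rats of other groups that had both kinds of array, the dim arrays differed from the brighter ones in the direction of the calls, by a median log2 of 0.58 (rats 3, 16, 21 and 22: 0.68, 0.13, 0.63 and 0.53), against a median size of the calls of 1.22. An effect of the day cannot be told apart from this with 1 bright rat: rat 9 stood at 0.47 over the 1024 probes called without it, and 7 bright rats of the other days between -0.18 and 0.12. The 10 splits of these 6 rats are too few for a share under 0.05 (real count 203, highest other 14).

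Without the dim arrays 1895 probes differed between the exposures, among them Cd36, Pkm and Mki67. Array series I held no sustained array. With it left out too, the 1895 probes had a median difference of log2 0.53 in the direction of the calls, against 0.59 with it. Of those measured there, 99.6% kept their direction. That fit holds only intermittent rats 8, 14 and 15, each the only rat of its day, and reuses arrays that gave the calls. In these rats the difference stood without series I. For the other intermittent rats, all on series I only, the series cannot be told apart from the exposure. For labelling strength the ratio of the spiked-in bacterial RNA to the gene probes was used. Both were amplified and labelled together, so a strength common to both cancels in this ratio. The ratio can thus show only a labelling difference between the spiked-in RNA and the gene probes. Such a difference was taken to need, as a cause, a score of these probes that rises with the ratio. Over 8 intermittent rats the correlation was -0.484 (exact p = 0.238), the other sign. A correlation within 1 exposure cannot test an offset between the exposures, so labelling strength stays open. Among 100 splits of the rats the real one gave the most calls (1895, highest other 1662, median of the others 6). That highest other split put 6 of the 8 intermittent rats and rat 22 together and so nearly repeats the real one. The splits also moved rats between days, and on all arrays 69 of 100 gave as many as the 1 real call. They therefore do not by themselves exclude chance. An effect of the exposure may stand behind part of these calls.

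The neutrophil list fell with the days of sustained hypoxia (median slope log2 -0.12, adjusted p = 2.4e-06; adjusted p = 0.11 with an estimated correlation), with Defa5, Mmp9 and S100a9 highest in the day-1 rat. Over the same days the skeletal and cardiac muscle lists fell with steeper median slopes (-0.41 and -0.24, adjusted p = 4.2e-05 and 3.5e-05; adjusted p = 0.34 with an estimated correlation for each), and carried-along tissue was not tested as an explanation. At the preset correlation the tables argue against dim arrays as the whole cause, since the list passed without them (adjusted p = 0.0029; adjusted p = 0.42 with an estimated correlation). A candidate explanation is 1 rat: without rat 16 the adjusted p was 0.31, and without any other single sustained rat it was at most 9.2e-06. Whether the slope belongs to sustained hypoxia stays open, since its difference from intermittent hypoxia had an adjusted p of 0.011 at the preset correlation and 0.55 with an estimated correlation.

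In tests for a single array far from the others of its group (9 tests; chance finds such an array in about 1 in 20 groups), the array of rat 12 at intermittent day 14 had a median intensity of 125, 20.4% of spots near background and a first principal component of 38.2. The array of rat 9 at intermittent day 7 had 7.64% of spots near background, the lowest of 4. These tests took the arrays of a group as independent, and the chance rate holds only for such arrays. Several day-14 arrays were repeats of rat 14, so the array of another rat could stand apart for that reason. Probe 14006 was noted because a test of the difference between the exposures passed (log2 -1.60, intermittent minus sustained).

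Among 100 splits of the rats, only the real one gave as many calls as the 5 of sustained hypoxia (highest other 1). The splits also moved rats between days and took room-air and exposed rats as alike, though room-air rats were means of more arrays. A small share therefore does not by itself exclude chance. Counting the real one, as many came in 40 of 100 splits for the 8 lists of sustained hypoxia (highest other 16). The shares were 74 of 100 for the 3 lists of intermittent hypoxia (highest other 12) and 69 of 100 for the 1 probe between the exposures (highest other 3620). For these results chance cannot be excluded. For the 0 probes of intermittent hypoxia (highest other 1377) and the 0 lists between the exposures (highest other 11), all 100 of 100 splits necessarily give as many, so that they decide nothing. Splits that called 1377 and 3620 probes point to a structure of the samples: the first set rats 9, 10 and 12 apart and the second rats 4, 6, 10, 11, 12, 19 and 22. Of these, rats 6, 10, 11 and 12 had only dim arrays and rat 22 had both kinds. Rats 4, 9 and 19 had no dim array. Without the dim arrays the real split gave the most calls of 100. It gave 105 for intermittent (highest other 58) and 91 for sustained hypoxia (highest other 33). Those highest other splits kept room-air rats 1 and 3 together, and 37 and 54 of the other splits called any probe. The same limits apply and the setting was chosen after the data were seen, so these splits do not by themselves exclude chance. Chance cannot be excluded there for the 4 lists of intermittent (82 of 100 splits gave as many) and the 6 of sustained hypoxia (49 of 100). The same holds for the 3 lists that differed between the exposures (74 of 100). The 10 splits are too few for a share under 0.05 for sustained days 1 to 7 (real count 3, highest other 1) and intermittent days 1 (0, highest other 0) and 14 (1, highest other 0).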

How the results depend on the processing

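The settings without dim arrays and with room-air arrays split by code were chosen after the data were seen. Where counts moved, the cause was not tested unless named. Counts are in the order intermittent, sustained and their difference over all days unless said. The number of arrays and rats limits the precision, and signals near background are compressed.

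Of the named genes under the other settings, 2383 values kept their direction and side of the threshold, 301 passed where the reported one did not, 60 no longer passed and 46 had the other sign, passing in neither setting; with a rat left out these numbers were 3304, 34, 125 and 27. Only a gene that passed in the reported fit could lose its call, and most of these values were of genes that did not pass. With each of 22 rats left out, losses per gene call ran from 1 (slope of Defa5 in sustained hypoxia) to 15 (Adamts1, sustained days 1 to 7). Genes named because they passed without the dim arrays count among the 301 by that choice. Called lists kept their call in 171 cases and lost it in 62 under other settings, and 213 and 29 with a rat left out. No result turned its direction with a passing test.

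With rat as a random block on arrays the counts were 206, 196 and 121, 221 for sustained days 1 to 7, 86, 116, 1522 and 117 for intermittent days 1, 3, 7 and 14, 16 and 56 for sustained days 14 and 30, 4 and 86 for the slopes in intermittent and sustained hypoxia and 3 for their difference; 5 lists were called for intermittent hypoxia and 5 for the difference. In this fit rats with more arrays weigh more.

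With the replicate number as a block the counts were 22, 24 and 33, 43 for sustained days 1 to 7, 74, 3, 967 and 72 for intermittent days 1, 3, 7 and 14, 3 and 7 for sustained days 14 and 30, 61 for the sustained slope and 3 for the difference of slopes, with 8 lists for intermittent hypoxia and 7 for the difference. The block ended the call of Heyl in sustained hypoxia (adjusted p = 0.057), of Prom1 at intermittent day 7 (0.079) and of the erythroid list in sustained hypoxia (0.39), and no other named call. The numbers do not pair the rats: arrays of different groups with the same number had a mean correlation of -0.0018 (270 pairs) against 0.0075 with different numbers (469 pairs), and 7 of 42 arrays were closest to one of their own number.

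With array series IV and V only the counts were 1, 19 and 0, 26 for sustained days 1 to 7, 2433, 4, 1 and 0 for intermittent days 1, 3, 7 and 14, 1 for sustained day 14 and 1 for the sustained slope, and 7, 5 and 6 lists. Series I alone gave 1 for intermittent hypoxia, 2 for its day 1 and 1 for its day 7. Series IV alone gave 15, 15 and 341, 19 for sustained days 1 to 7, 2149 and 446 for intermittent days 1 and 7, 1 for sustained day 14, 1369 and 0 for the 2 slopes, and 5 and 3 lists for sustained hypoxia and the difference. Series V alone gave 1, 10 and 0, 11 for sustained days 1 to 7, 2 and 1 for intermittent days 3 and 7, 4 for sustained day 30, 4 for the sustained slope, and 5, 4 and 1 lists. These settings hold fewer rats, and the 2433 and 2149 calls of intermittent day 1 and the 446 of day 7 each rest on 1 dim array (rats 6 and 11).

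Weighting rats by their arrays gave 37, 74 and 3, 60 for sustained days 1 to 7, 1594 and 31 for intermittent days 7 and 14, 1 and 6 for sustained days 14 and 30 and 4 for the sustained slope. Leaving out the dim arrays gave 105, 91 and 1895, 116 for sustained days 1 to 7, 73, 217 and 36 for intermittent days 1, 3 and 14, 166 and 5 for sustained days 14 and 30, 31 for the sustained slope and 3 lists for the difference. With series IV and V only as well it gave 35, 230 and 890, 216 for sustained days 1 to 7, 282 and 15 for intermittent days 3 and 14, 228 and 8 for sustained days 14 and 30, 14 for the sustained slope, and 6 and 2 lists for intermittent hypoxia and the difference. Room-air arrays split by code gave 15, 37 and 2, 24 for sustained days 1 to 7, 4, 2502 and 9 for intermittent days 3, 7 and 14 and 1 for sustained day 14; this counts 3 control rats as more samples.

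Median centring gave 2 for sustained hypoxia. Pooling the days gave 0 for sustained hypoxia, 9 for the difference and 3 lists for sustained hypoxia. Normexp background gave 4 for the difference, 6 for sustained days 1 to 7, 1 for intermittent day 3, 11 for the sustained slope and 2 for the difference of slopes. Keeping probes detected in all rats gave 0 for the difference, 341 and 2 for intermittent days 7 and 14, 1 for sustained day 14, 0 for the sustained slope, and 5 and 3 lists for sustained hypoxia and the difference. The variance model without trend and robust fit gave 2 for the difference. The authors' processed values gave 5 for sustained days 1 to 7, 2 for intermittent day 7, 9 for the sustained slope, 2 for the difference of slopes and 7 lists for intermittent hypoxia. No filter on dim probes gave 5 for sustained days 1 to 7, no array-series adjustment 340 for intermittent day 7 and 2 lists for the difference, and the day without a logarithm 0 for the sustained slope. Keeping all spots gave 7 lists for intermittent hypoxia and 2 for the difference, and all probes of a gene 2 for the difference. An estimated correlation and fry each gave 0 lists for intermittent and 0 for sustained hypoxia.

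With each rat left out in turn the counts ranged from 0 to 2, 0 to 9 and 0 to 398, 0 to 6 for sustained days 1 to 7, 0 to 54, 0 to 2, 0 to 1024 and 0 to 4 for intermittent days 1, 3, 7 and 14, 0 to 2 and 0 to 0 for sustained days 14 and 30, 0 to 3, 0 to 4 and 0 to 0 for the slopes and their difference, and 3 to 5, 4 to 9 and 0 to 3 lists. Groups left with 1 rat were assumed to vary like the others.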

Other observations

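The list tests of the slopes and the genes named here were chosen after the results were seen.

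RT1-Bb, a chain of MHC class II, stood at log2 6.55, 7.81 and 7.56 in the 3 room-air rats. In sustained hypoxia it stood between 3.27 and 5.81 in 7 rats (log2 -3.36, SE 0.85, adjusted p = 0.55 on all arrays). In intermittent hypoxia it stood at 7.73 in rat 9 and 9.52 in rat 10, and between 3.22 and 4.02 in the other 9 rats measured. Without the dim arrays the differences from room air were -3.40 in sustained and -3.11 in intermittent hypoxia (SE 0.30 each). That setting drops rat 10 and leaves rat 9 as the only rat of its day, so that their high values no longer widen the SE. RT1-Bb was near background on 0 of 14 room-air, 13 of 16 intermittent and 9 of 12 sustained arrays. The MHC class II list of 6 genes had medians of -0.08 in intermittent and -0.08 in sustained hypoxia and passed in neither (adjusted p = 0.75 and 0.63).

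Alox15 stood at log2 9.29 and 10.24 in the 2 rats of intermittent day 3 and at 8.40 in the rat of sustained day 3, against values between 5.35 and 5.83 in the 3 room-air rats. It did not pass at intermittent day 3 (adjusted p = 0.39), and sustained day 3 was not tested on its own.

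The T and natural killer cell list fell with the days of sustained hypoxia (23 members, median slope log2 -0.12, adjusted p = 2.7e-07; adjusted p = 0.11 with an estimated correlation), and 6 members had falling slopes adjusted over the list alone. Over the same days the skeletal muscle (median slope -0.41, adjusted p = 4.2e-05), cardiac muscle (-0.24, 3.5e-05), glycolysis (-0.11, 0.012), cell cycle (-0.11, 0.016) and heat shock (-0.07, 0.022) lists fell, and the alveolar type I (0.08, 0.022) and cartilage (0.09, 0.037) lists rose, each with an adjusted p of at least 0.22 with an estimated correlation. The T and natural killer cell list also fell with the days of intermittent hypoxia (median slope -0.12, adjusted p = 0.015; adjusted p = 0.55 with an estimated correlation). The difference of the slopes did not pass (adjusted p = 0.066). With the days of intermittent hypoxia the matrix (median slope 0.11, adjusted p = 0.015), smooth muscle (0.12, 0.015), glucocorticoid response (0.10, 0.020) and vasoactive (0.04, 0.034) lists rose, each with an adjusted p of at least 0.54 with an estimated correlation.

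Without the dim arrays the alveolar type II list (median log2 0.29, adjusted p = 0.0077), the alveolar type I list (0.47, adjusted p = 0.0065) and the glucocorticoid response list (0.18, adjusted p = 0.0068) were higher in intermittent than in sustained hypoxia, each with an adjusted p of 0.25 with an estimated correlation.

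Of the 14 room-air arrays 8 carry an A in their code. Deviations from the rest were correlated at a mean of 0.46 between arrays of 1 rat with the same code (10 pairs) and 0.16 between those with another code (16 pairs). Over all arrays, dim ones included, the ratio of the spiked-in bacterial RNA to the gene probes was 5.71 in room air, 6.55 in intermittent and 5.21 in sustained hypoxia (exact p = 0.556 and 0.525 against room air, and 0.161 between the exposures). Without the dim arrays its log2 stood at 2.24, 2.78, 3.12, 3.16, 2.90, 3.11, 3.23 and 3.28 in the intermittent rats. In the sustained rats it stood at 2.98, 2.29, 2.69, 1.99, 2.03, 2.52 and 2.62. The intermittent values were mostly the higher ones, and this difference was not tested.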
